A study of Homo sapiens with 8 samples.

How the data were processed

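Gene expression was measured by RNA sequencing in 8 libraries of DU145 cells, 2 from each of 4 groups that received a scrambled siRNA, a pool against YAP, a pool against TAZ or both pools for 48 h. Per the labels, RNA was extracted with TRIzol and libraries were made with a stranded poly(A) kit (TruSeq Stranded mRNA). Amounts and sequences of the siRNAs were not given in the sources used here. The values are whole-number counts per gene as the authors deposited them, with no normalization, in 1 table of 57820 genes, per the file headers laid out as featureCounts writes it and annotated with GENCODE on hg19. The submitters' processing notes name Trim Galore, STAR 2.6, featureCounts and Subread with the builds hg19 and GRCh37.p13, without roles or settings. The strand setting of the counting and the treatment of reads that match several genes were not given in the sources used here. Genes on overlapping strands and close paralogs could therefore share or lose reads. Among the genes named under the rule given here and printed in the results, the largest shares of exon bases overlapping another annotated gene on either strand were those of MYL9 (57.7%), CCNE2 (37.1%), SELENOP (36.1%), MTHFD2 (33.2%), WWC2 (27.2%), TYMS (26.2%), RPS2 (25.6%), VIM (25.4%), AXIN2 (25.3%), KRT18 (24.7%), RNF43 (20.3%) and JUP (17.1%), whose values are uncertain. Gene length per the file headers is the summed exon length and was used only to describe genes.

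Groups and replicate numbers came from the labels, and each of the 8 count columns matched the title of a single sample. Gene coordinates are those of the deposited table (hg19). Symbols and gene types came from a GENCODE annotation of a later build, matched by identifier without coordinates, for 51996 of the 57820 identifiers. The replicates of each group differed by more than sampling noise, with a chi-square per degree of freedom of 9.00 for scrambled, 5.32 for the YAP pool, 8.05 for the TAZ pool and 7.32 for both pools, so each library was counted as its own replicate. Total counts ran from 23638180 to 32328751 per library, and the 10 most abundant genes took 4.29% to 4.98% of them. The scaling factors ran from 0.971 to 1.046 and differed by group. They were 0.971 and 0.981 for scrambled, 0.988 and 0.972 for the YAP pool, 1.013 and 1.008 for the TAZ pool, and 1.046 and 1.024 for both pools.

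All 8 libraries were fitted together with 1 coefficient per group in edgeR 4.0.16 under R 4.3.3, after filterByExpr had left 17192 genes (13431 of them protein-coding), with TMM scaling and the quasi-likelihood test. With 2 libraries per group this leaves 4 residual degrees of freedom, supported by 9.88 prior degrees of freedom shared across genes, and the common biological coefficient of variation was 0.0700. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. The contrasts were each knockdown against scrambled, the knockdowns against each other, and non-additivity, which is the log2 effect of both pools minus the sum of the effects of the single pools. Fold changes are given with standard errors on the log2 scale, and levels as CPM, counts scaled to the TMM library size, mean ± SD.

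Gene lists were tested with camera (limma 3.58.1) against all other tested genes with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation. They were 31 lists with 548 measured genes, 29 of them large enough to test, covering signalling, cell cycle, metabolism, adhesion, prostate cell identity, other cell types and RNA quality. Members were also adjusted over the list alone. The groups, tests, contrasts, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. That rule names YAP1, WWTR1, CCN2, CCN1, ANKRD1, AMOTL2 and AXL always. For each comparison with scrambled it takes the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 2 log2 CPM whose knockdown libraries both lie beyond both scrambled libraries. It adds up to 4 members of each list with the smallest adjusted p, and the 5 genes with the smallest adjusted p in each test between knockdowns. Further list members named in the text were chosen after their values were seen.

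The procedure was tested on simulated data with the means and depths of these libraries and genes changed by known folds, of which 16848 genes passed the filter. In the comparison of the YAP pool with scrambled, 56.1%, 64.2% and 95.3% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 7.24% of the calls were false. For the TAZ pool the recoveries were 56.7%, 69.7% and 87.9% with 4.70% false calls, for both pools 62.1%, 76.2% and 92.4% with 6.83%, and for non-additivity 48.5%, 63.5% and 86.4% with 4.76%. A shift planted in the mitosis list was recovered and 0 other lists were called. Simulated genes varied independently of each other, so the error of the list test for correlated genes was not checked. Each simulated group held 195 to 199 changed genes among those tested, far fewer than were called in the real libraries, so the shares of false calls may differ there.

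Alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, only the libraries of the groups compared, the replicate number as a block, a threshold of 1 on the log2 fold change, and each library left out in turn, where the lone library of a group was assumed to vary like the other groups. Scaling by library totals alone was added after seeing the data. Overlaps between comparisons that share the scrambled libraries were set beside 20 simulations of unchanged groups. For siRNA effects through short matches, every 7-base word found in the 3′ untranslated regions of at least 100 genes (15991 words, 13233 genes, 98.5% of the protein-coding genes tested) was tested for lower expression with the length and GC content of the 3′ untranslated region in the model, with 100 permutations of the genes. With 2 libraries per group no test over other splits of the libraries was run, and differences between groups cannot be checked for batches, since the labels give none.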

Results

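RNA sequencing was carried out on DU145, an androgen-independent line of human prostate cancer cells, 48 h after transfection with small interfering RNAs (siRNAs), short double-stranded RNAs that lower the level of a matching mRNA. The labels name pools of siRNAs against YAP, against TAZ or against both, and a scrambled control, with 2 libraries in each of the 4 groups. YAP and TAZ, encoded by YAP1 and WWTR1, are paralogous transcriptional coactivators that are held in check by the Hippo kinases and bind DNA through TEAD factors. The source label describes the material as prostate cancer organoid, whereas the cell line label gives DU145, grown in a medium used for human organoids. Total counts over genes were 28910978 and 28725857 in the scrambled libraries, 23638180 and 30102804 with the YAP pool, 29193444 and 31670362 with the TAZ pool, and 28888736 and 32328751 with both pools. The first principal component held 58.0% of the variance and set the libraries with both pools (61.5 and 66.7) apart from the rest. On it the TAZ pool (-2.05 and 2.41) lay between these and the scrambled (-38.9 and -28.1) and YAP pool libraries (-33.8 and -27.8). The component after it held 14.4% and set the YAP pool apart from the TAZ pool and the scrambled libraries. Because the labels do not say that the replicates came from separate cultures, p-values measure the spread between these libraries only, which may be technical. Values in parentheses after gene names are log2 fold changes against the scrambled libraries unless another comparison is named, and a gene rose or fell where its adjusted p passed the threshold given with the methods.

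The targeted genes were examined in every library as a check of the labels. YAP1 (ENSG00000137693.9, chromosome 11, 101981192 to 102104154, plus strand, hg19, counted over all annotated exons including untranslated regions) stood at 219 ± 1.49 CPM (counts scaled to library size) in the scrambled libraries and at 14.9 ± 0.457 with the YAP pool (SD, n = 2 each). Its log2 fold change was -3.87 ± 0.08 (SE) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 2.68e-12), which left 6.82% of the scrambled level. With both pools YAP1 stood at 18.8 ± 0.466 CPM, a log2 fold change of -3.54 ± 0.08 and 8.58% of the scrambled level. WWTR1 (ENSG00000018408.10, chromosome 3, 149235022 to 149454501, minus strand, hg19) went from 155 ± 7.12 to 29.1 ± 5.30 CPM with the TAZ pool and 43.2 ± 14.2 with both pools (SD, n = 2 each). These levels were 18.8% and 28.0% of the scrambled level, with log2 fold changes of -2.41 ± 0.17 and -1.84 ± 0.16. Each pool therefore lowered its own target in every library it was used in. YAP1 was also slightly lower with the TAZ pool (-0.29 ± 0.07, adjusted p = 0.0121 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a call that was lost without scrambled replicate 1, without scrambled replicate 2 or without TAZ pool replicate 1. WWTR1 stood at 203 ± 7.73 CPM with the YAP pool (0.39 ± 0.15), which did not pass the test. With the pools combined YAP1 was 0.33 ± 0.09 and WWTR1 0.57 ± 0.17 higher on the log2 scale than with its own pool alone. The WWTR1 difference leaned on single libraries, with 0.18 ± 0.13 (adjusted p = 0.359) without replicate 2 of both pools and 0.39 ± 0.19 (adjusted p = 0.144) without TAZ pool replicate 1, and it did not pass in DESeq2 (adjusted p = 0.117) or with the compared libraries alone (0.0565). The YAP1 difference did not pass without YAP pool replicate 1 (0.0610).

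**Figure D1:**
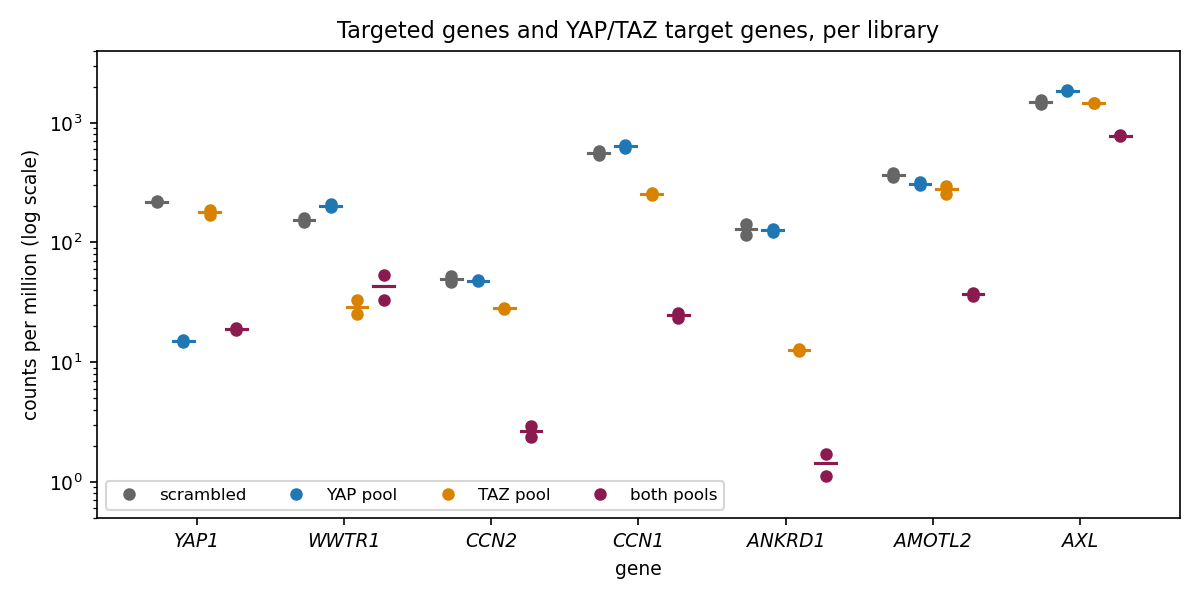
CPM (counts scaled to library size, log axis) of YAP1, WWTR1 and 5 established YAP/TAZ target genes in each of the 8 libraries, with points for libraries, short lines for group means and colours for the 4 groups. ANKRD1, CCN1 and CCN2 were lowest with both pools, lower with the TAZ pool than in the scrambled libraries, and did not pass the test with the YAP pool.

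The comparison of the YAP pool with the scrambled control asks which transcripts change when YAP alone is lowered. TAGLN, an actin-binding protein of contractile cells, fell (-2.09 ± 0.12), as did 6 of 19 actin and SRF genes in all, a list that did not pass with an estimated correlation (camera adjusted p = 0.0932). IFIT1, a sensor of foreign RNA, rose (1.02 ± 0.10), with 16 of 26 interferon-stimulated genes and 10 of 16 genes induced by ERK signalling. The classical YAP/TAZ target genes CCN1, CCN2 and ANKRD1 did not pass the test, at 0.18, -0.04 and -0.02. Of 17192 genes tested, 1092 rose and 1120 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 134 and 100 changed by more than 1 on the log2 scale. The largest rises were those of SLCO2B1, an organic anion transporter (2.28 ± 0.22), LIPH, a phospholipase (2.27 ± 0.17), VGF, a secreted neuropeptide precursor (1.93), NTSR1, the neurotensin receptor (1.88), CD22 (1.78), LAT2 (1.60), MYH15 (1.52), the basal keratin KRT15 (1.49), TNFRSF1B, a receptor for TNF (1.41), and MMP1, a collagenase (1.40). Beside YAP1, the largest falls were those of CEMIP, which binds and degrades hyaluronan (-2.41 ± 0.12), SMIM14 (-2.15), TAGLN, MRPS6 of the mitochondrial ribosome (-2.03), NLRP12 (-1.58), the kinesin KIF3B (-1.53), DTX4 (-1.48), MEGF9 (-1.41) and IVL, a protein of the cornified envelope (-1.36). The call of IVL was lost without scrambled replicate 2 (-1.18).

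Of 26 measured interferon-stimulated genes, 16 rose and 0 fell with the YAP pool, or 18 and 1 adjusted over the list alone, among them OAS3 (0.92), IFIT1, IFIT2 (0.84) and OASL (0.84). Camera with Benjamini-Hochberg adjustment placed this list above the other genes (adjusted p = 6.65e-19, and adjusted p = 0.0143 with an estimated correlation). Among 16 genes induced by ERK signalling, 10 rose and 0 fell, the same numbers adjusted over the list alone, including the phosphatases DUSP5 (1.32) and DUSP4 (1.02), the feedback inhibitor SPRY4 (1.06) and the transcription factor ETV4 (0.75). This list passed camera with Benjamini-Hochberg adjustment (adjusted p = 9.16e-09, and adjusted p = 0.0404 with an estimated correlation). NF-kB targets and cytokines showed 8 rises and 0 falls among 16 (11 and 0 adjusted over the list alone), such as CSF2, a myeloid growth factor (1.80), TNFAIP2 (0.81), BIRC3, an inhibitor of apoptosis (0.58), and NFKB2 (0.44). Camera on the NF-kB genes gave a Benjamini-Hochberg adjusted p = 1.27e-08, and adjusted p = 0.154 with an estimated correlation. Regulators of apoptosis showed 6 rises and 0 falls among 19 (8 and 3 adjusted over the list alone), led by the pro-apoptotic BMF (1.13) and including BAK1 (0.51). Camera on the apoptosis genes gave a Benjamini-Hochberg adjusted p = 0.0131, and adjusted p = 0.154 with an estimated correlation.

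Of 19 genes of the actin cytoskeleton and SRF targets, 6 fell and 0 rose with the YAP pool (7 and 0 adjusted over the list alone). They included TAGLN, MYL9, a myosin light chain whose exons largely overlap another annotated gene (-1.22), the tropomyosin TPM1 (-0.77) and CNN2 (-0.72). Camera on the actin and SRF genes gave a Benjamini-Hochberg adjusted p = 1.62e-09, and adjusted p = 0.0932 with an estimated correlation. ATF4 targets and genes of amino acid synthesis and transport showed 8 falls and 0 rises among 22 (12 and 1 adjusted over the list alone), such as SLC7A5, a transporter of large neutral amino acids (-0.79), ALDH1L2 (-0.68), PCK2 (-0.65) and PSAT1 (-0.35). Camera on the ATF4 genes gave a Benjamini-Hochberg adjusted p = 1.13e-06, and adjusted p = 0.154 with an estimated correlation. Hypoxia-induced and glycolytic genes showed 7 falls and 0 rises among 24 (9 and 0 adjusted over the list alone), such as NDRG1 (-0.95), PFKFB4 (-0.81) and VEGFA (-0.70). Camera on the hypoxia genes gave a Benjamini-Hochberg adjusted p = 7.41e-05, and adjusted p = 0.154 with an estimated correlation. The YAP/TAZ target signature showed 8 falls and 3 rises among 21 (9 and 5 adjusted over the list alone), with IGFBP3 (-1.29), FJX1 (-0.93), CCDC80 (-0.89) and F3 (-0.50) among the falls and NUAK2 (0.40), PTPN14 (0.44) and AXL (0.31) the rises. Its camera test gave adjusted p = 0.00425 and adjusted p = 0.29 with an estimated correlation, and the call of AXL was lost without YAP pool replicate 2. TGF-beta and BMP targets showed 5 falls and 1 rise among 13, the same adjusted over the list alone, such as ID2 (-0.67), TGFBI (-0.67) and PMEPA1 (-0.56). Camera on the TGF-beta genes gave a Benjamini-Hochberg adjusted p = 0.013, and adjusted p = 0.46 with an estimated correlation. The receptor gene ERBB2 fell (-0.94) and TGFA, a ligand of EGFR, rose (1.09), and the remaining lists did not pass camera.

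The YAP pool counts rested in part on single libraries. Rises fell to 625 without scrambled replicate 1, 643 without scrambled replicate 2, 592 without YAP pool replicate 1 and 442 without YAP pool replicate 2, and the falls to 698, 645, 533 and 495 in the same order. Without YAP pool replicate 2 the counts were 6 rises for ERK-induced genes, 5 for NF-kB targets and 3 for apoptosis, and 4 falls for ATF4 targets, 4 for hypoxia-induced genes and 5 for the YAP/TAZ signature with 1 rise. Without YAP pool replicate 1 there were 4 falls among YAP/TAZ targets, 4 among hypoxia-induced genes and 3 among TGF-beta targets, and without scrambled replicate 1 there were 6 rises among ERK-induced genes. The 1 rise among TGF-beta targets was not called without scrambled replicate 1 or YAP pool replicate 2, where 0 were. By camera with Benjamini-Hochberg adjustment, the apoptosis list gave adjusted p = 0.0529 without scrambled replicate 1, and the TGF-beta list 0.168 without scrambled replicate 2 and 0.0849 without YAP pool replicate 1.

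The TAZ pool was compared with the scrambled control to ask the same of TAZ. Established YAP/TAZ targets fell, led by ANKRD1, a nuclear protein of the stretch response (-3.35 ± 0.12), with falls in 14 of 21 signature genes, 17 of 32 mitotic genes and 36 of 80 cytosolic ribosomal protein genes. Rises were called in 12 of 26 interferon-stimulated and 7 of 14 histone genes. With an estimated correlation the mitotic, ribosomal, interferon and histone lists did not pass camera (adjusted p = 0.544, 0.663, 0.0547 and 0.35), and without scrambled replicate 1 there were 3 ribosomal falls. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1482 genes rose and 1475 fell, 144 and 132 of them by more than 1 on the log2 scale. The largest rises were those of the calcium channel gene CACNA1G (2.67 ± 0.21), TSPAN2 (1.77), the WNT enhancer RSPO3 (1.75), the aldo-keto reductases AKR1C3 (1.74) and AKR1B10 (1.59), BMF (1.73), SLCO2B1 (1.71), RGS17 (1.68), CNTN1 (1.64) and the selenium carrier SELENOP (1.60). Values of the aldo-keto reductases are uncertain because close paralogs can share reads, and those of SELENOP because 36.1% of its exon bases overlap another annotated gene and the strand setting of the counting was not stated. Beside ANKRD1 and WWTR1, the largest falls were those of IGFBP3, a binding protein of insulin-like growth factors (-2.11), STK31 (-2.10), the caveolar protein CAVIN2 (-1.86), ANKRD2 (-1.81), NTN4 (-1.65), WNT5B (-1.55), the co-chaperone FKBP4 (-1.42) and TERT, the catalytic subunit of telomerase (-1.40).

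Of 21 genes of the YAP/TAZ target signature, 14 fell and 1 rose with the TAZ pool (15 and 1 adjusted over the list alone), including CCN1 (-1.13), CCDC80 (-1.11), TGFB2 (-1.04) and CCN2 (-0.80), with NT5E the rise (0.42). Camera with Benjamini-Hochberg adjustment gave adjusted p = 4.81e-27, and adjusted p = 0.0424 with an estimated correlation. AMOTL2, a scaffold that binds YAP, also fell (-0.40), a call lost without TAZ pool replicate 2 (-0.29), and AXL, a receptor tyrosine kinase, did not pass (-0.03). Components of the Hippo pathway showed 11 falls and 1 rise among 25 (13 and 1 adjusted over the list alone), such as WWC1 (-0.97), WWC2 (-0.73), TEAD1 (-0.62) and NF2 (-0.50). Camera on the Hippo genes gave a Benjamini-Hochberg adjusted p = 1.27e-05, and adjusted p = 0.39 with an estimated correlation. Among 32 genes of G2 and mitosis 17 fell and 0 rose (24 and 0 adjusted over the list alone), including CDC20 (-0.74), KIF23 (-0.59), HMMR (-0.58) and AURKA (-0.47). Camera on the mitotic genes gave a Benjamini-Hochberg adjusted p = 3.12e-11, and adjusted p = 0.544 with an estimated correlation. DNA replication genes showed 9 falls and 3 rises among 40 (12 and 3 adjusted over the list alone), such as GINS2 (-0.72), TYMS (-0.65) and RRM1 (-0.63). Camera on the replication genes gave a Benjamini-Hochberg adjusted p = 0.00605, and adjusted p = 0.74 with an estimated correlation. Of 80 cytosolic ribosomal protein genes 36 fell and 0 rose (57 and 0 adjusted over the list alone), among them RPS27A (-0.75), RPS24 (-0.49) and RPL5 (-0.37). Camera on the ribosomal protein genes gave a Benjamini-Hochberg adjusted p = 7.31e-14, and adjusted p = 0.663 with an estimated correlation. Hypoxia-induced and glycolytic genes showed 14 falls and 0 rises among 24 (17 and 2 adjusted over the list alone), including the glucose transporter SLC2A1 (-0.73), the hexokinase HK2 (-0.63), NDRG1 (-0.56) and BNIP3 (-0.45). Camera on the hypoxia genes gave a Benjamini-Hochberg adjusted p = 2.82e-07, and adjusted p = 0.12 with an estimated correlation.

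Interferon-stimulated genes showed 12 rises and 0 falls among 26 with the TAZ pool (15 and 0 adjusted over the list alone), such as MX2 (1.52), OAS2 (1.19), OASL (0.69) and IFIT2 (0.55). Camera on the interferon genes gave a Benjamini-Hochberg adjusted p = 3.69e-07, and adjusted p = 0.0547 with an estimated correlation. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, showed 7 rises and 0 falls among 14, the same adjusted over the list alone, including H2AC6 (0.97), H1-2 (0.80) and H2BC4 (0.78). Camera on the histone genes gave a Benjamini-Hochberg adjusted p = 1.43e-05, and adjusted p = 0.35 with an estimated correlation. ERK-induced genes showed 7 rises and 2 falls among 16 (8 and 2 adjusted over the list alone), with DUSP4 (1.25) and SPRY2 (0.64) higher and DUSP1 (-0.98) lower, and the list did not pass camera (adjusted p = 0.0921 with Benjamini-Hochberg adjustment). The counts were 3 and 2 without scrambled replicate 1, 6 and 1 without scrambled replicate 2 and 4 and 1 without TAZ pool replicate 2. Other list members that changed were CDKN1A, an inhibitor of cyclin-dependent kinases (0.79), the death receptor TNFRSF10B (-0.67), BIRC3 (-1.02), the Notch target HES1 (1.11), the matrix protein TNC (1.19) and the simple-epithelial keratins KRT8 (-1.13) and KRT18 (-0.86).

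The TAZ pool counts also leaned on single libraries. Rises fell to 700 without scrambled replicate 1 and 910 without TAZ pool replicate 2, and falls to 682 without scrambled replicate 1, 908 without TAZ pool replicate 1 and 788 without TAZ pool replicate 2. Without scrambled replicate 1 there were 8 falls among mitotic genes, 3 among ribosomal protein genes, 8 among hypoxia-induced genes, 7 among Hippo components and 5 among DNA replication genes, and 7 rises among interferon-stimulated and 3 among histone genes. Without TAZ pool replicate 2 the falls were 10 for mitotic, 5 for ribosomal protein, 7 for hypoxia-induced and 5 for DNA replication genes, with 3 rises for histones, and without TAZ pool replicate 1 there were 8 falls among hypoxia-induced genes. The 3 rises among DNA replication genes became 1 without scrambled replicate 2. The camera test of DNA replication gave adjusted p = 0.287 with Benjamini-Hochberg adjustment without scrambled replicate 1. With libraries scaled by their totals alone, an alternative chosen after seeing the data, 1952 genes rose and 1098 fell, so that 64.0% of the calls were rises against 50.1%, and 23 ribosomal protein genes fell.

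Libraries with both pools were compared with the scrambled control to ask what changes when YAP and TAZ are lowered together. Single YAP/TAZ targets were among the genes with the largest falls, with ANKRD1 at -6.48 ± 0.15, CCN1, a secreted matrix protein, at -4.51 ± 0.09, and CCN2, a related matrix protein, at -4.21 ± 0.12. Mean levels of ANKRD1 were 129 CPM in the scrambled libraries, 127 with the YAP pool, 12.6 with the TAZ pool and 1.43 with both. All 32 mitotic genes of the list fell, as did 77 of 80 cytosolic ribosomal protein genes, and 24 of 26 interferon-stimulated genes rose. With an estimated correlation the mitotic and ribosomal lists did not pass camera (adjusted p = 0.222 and 0.481). The pro-apoptotic BMF rose by 4.59 ± 0.15 on the log2 scale and the cell cycle inhibitor CDKN1A by 1.98 ± 0.08. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4365 genes rose and 4372 fell, which is 50.8% of the genes tested, and 1459 and 980 changed by more than 1 on the log2 scale. After BMF, the largest rises were those of the aquaporin AQP3 (4.35), the aldo-keto reductases AKR1C3 (4.33), AKR1B10 (4.15) and AKR1C1 (3.64), which are uncertain as paralogs, the collagen-binding integrin ITGA11 (4.29), SELENOP (4.16), S100A9, a calcium-binding protein of inflamed epithelium and myeloid cells (4.08), LIPH (3.93) and the bradykinin receptor BDKRB2 (3.74). After ANKRD1, the largest falls were those of ANKRD2 (-5.15), CCN1, CCN2, the peptide hormone APLN (-3.96), CCBE1 (-3.88), PEAR1 (-3.75), STK31 (-3.73), the tight junction claudin CLDN11 (-3.66) and CAVIN2 (-3.60). With libraries scaled by their totals alone, 5164 genes rose and 3546 fell, so that 59.3% of the calls were rises. That scaling gave 3 rises and 1 fall for ErbB receptors and ligands, 8 and 4 for apoptosis, 5 and 10 for actin and SRF genes and 7 and 0 for mitochondrial genes.

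**Figure D2:**
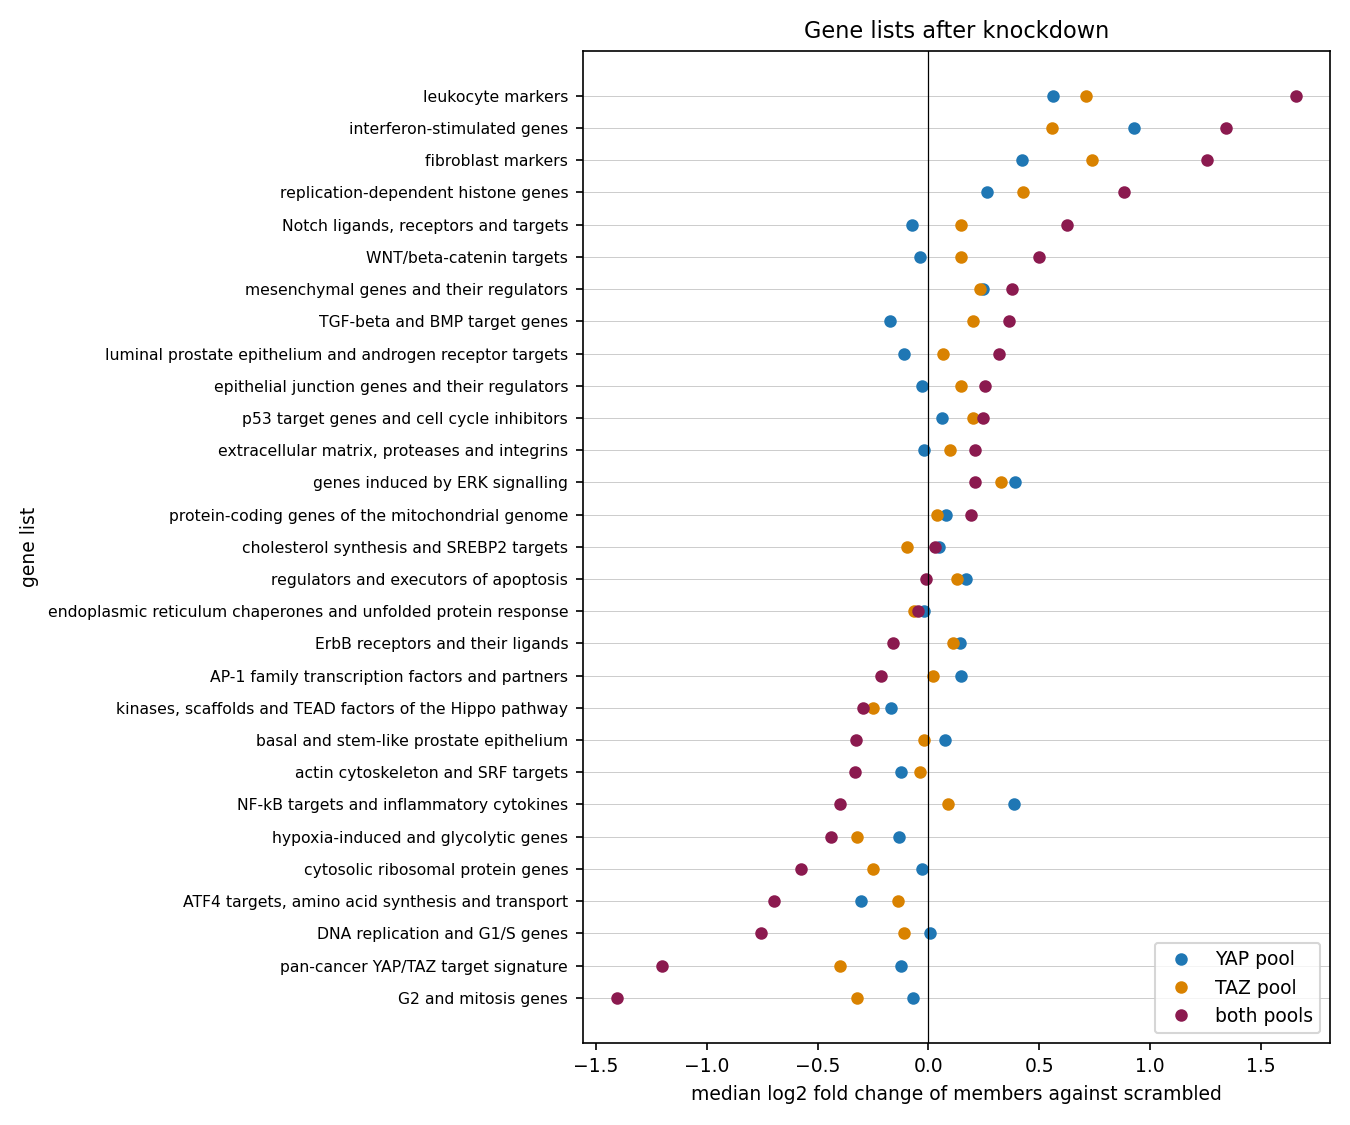
Median log2 fold change against the scrambled libraries (x axis) of the measured members of the 29 tested gene lists (y axis), with 1 point per comparison coloured by siRNA pool. With both pools the G2 and mitosis list had a median of -1.41 and the interferon-stimulated genes 1.34, and the medians of the apoptosis and endoplasmic reticulum lists with both pools and of the actin and basal lists with the TAZ pool turned sign with libraries scaled by their totals alone.

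Of 21 YAP/TAZ signature genes 20 fell with both pools and 1, NT5E, rose (0.68), the same adjusted over the list alone, with a median of -1.20 and AMOTL2 at -3.31. Camera with Benjamini-Hochberg adjustment gave adjusted p = 7.63e-39, and adjusted p = 0.0115 with an estimated correlation. AXL fell by 0.93. Hippo components showed 14 falls and 4 rises among 25, the same adjusted over the list alone, with WWC1 (-2.17), the TEAD factor TEAD4 (-1.60) and the kinase LATS2 (-1.31) among the falls. Camera on the Hippo genes gave a Benjamini-Hochberg adjusted p = 1.07e-06, and adjusted p = 0.266 with an estimated correlation. AP-1 factors went both ways, with 5 rises and 4 falls among 13, the same adjusted over the list alone (camera adjusted p = 0.438), including FOSL1 (-1.89), MAFF (-1.71) and JUND (1.17). ERK-induced genes showed 8 rises and 5 falls among 16, the same adjusted over the list alone (camera adjusted p = 0.816), with DUSP4 (2.19) and DUSP6 (1.62) higher and DUSP1 (-1.92) and MYC (-0.99) lower. ErbB receptors and ligands showed 3 rises and 4 falls among 9, the same adjusted over the list alone (camera adjusted p = 0.938), with ERBB3 higher (0.57) and HBEGF lower (-1.07), and the counts were 3 and 2 without scrambled replicate 2 and 2 and 1 without replicate 1 of both pools. The falls among ERK-induced genes were 3 without that same library.

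Mitotic genes fell without exception in the list, 32 of 32 and 32 adjusted over the list alone, with a median of -1.41 and examples in HMMR (-1.83), KIF23 (-1.79), CENPF (-1.48) and TOP2A (-1.45). Camera with Benjamini-Hochberg adjustment gave adjusted p = 9.79e-41, and adjusted p = 0.222 with an estimated correlation. DNA replication genes showed 35 falls and 2 rises among 40, the same adjusted over the list alone, including TK1 (-1.69), CDC45 (-1.51), MCM10 (-1.40) and TYMS (-1.11). Camera on the replication genes gave a Benjamini-Hochberg adjusted p = 5.25e-16, and adjusted p = 0.269 with an estimated correlation. The rises were the cyclins CCNE1 (0.49) and CCNE2 (0.44, uncertain because its exons overlap another gene), of which 1 was called without scrambled replicate 2. Of 80 cytosolic ribosomal protein genes 77 fell and 0 rose, the same adjusted over the list alone, such as RPL22L1 (-1.34), RPS27A (-0.97) and, uncertain for overlapping exons, RPS2 (-1.09). Camera on the ribosomal protein genes gave a Benjamini-Hochberg adjusted p = 3.18e-16, and adjusted p = 0.481 with an estimated correlation. p53 targets and cell cycle inhibitors showed 10 rises and 3 falls among 20, the same adjusted over the list alone, including TP53INP1 (2.22), CDKN1A and the pro-apoptotic BBC3 (1.97). Camera on the p53 genes gave a Benjamini-Hochberg adjusted p = 0.0162, and adjusted p = 0.523 with an estimated correlation. This call was lost without scrambled replicate 2 (camera adjusted p = 0.0714) and without replicate 1 of both pools (0.0599), and the falls were 1 without scrambled replicate 1. Regulators of apoptosis showed 5 rises and 5 falls among 19, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.479), with BMF and BCL2L11 (1.89), both pro-apoptotic, higher and the anti-apoptotic BIRC3 (-1.27) and BCL2L1 (-0.76) lower.

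Interferon-stimulated genes showed 24 rises and 0 falls among 26, the same adjusted over the list alone, with a median of 1.34 and examples in MX2 (2.66), OAS2 (2.55), OASL (1.38) and MX1 (1.24). Camera with Benjamini-Hochberg adjustment gave adjusted p = 1.99e-09, and adjusted p = 0.0314 with an estimated correlation. NF-kB targets showed 2 rises and 8 falls among 16, the same adjusted over the list alone (camera adjusted p = 0.0859), with CXCL5 (-1.14) and NFKB2 (-0.63) lower, and 0 rises without scrambled replicate 1. ATF4 targets and amino acid genes showed 14 falls and 4 rises among 22, or 15 and 4 adjusted over the list alone, including SLC7A5 (-1.54), the asparagine synthetase ASNS (-1.44), PSAT1 (-1.17) and, uncertain for overlapping exons, MTHFD2 (-1.12). Camera on the ATF4 genes gave a Benjamini-Hochberg adjusted p = 1.03e-05, and adjusted p = 0.248 with an estimated correlation. Hypoxia-induced and glycolytic genes showed 15 falls and 2 rises among 24, or 15 and 3 adjusted over the list alone, including SLC2A1 (-1.66), HK2 (-1.22) and PFKFB3 (-0.91). Camera on the hypoxia genes gave a Benjamini-Hochberg adjusted p = 0.000407, and adjusted p = 0.248 with an estimated correlation. Cholesterol synthesis genes showed 9 rises and 1 fall among 24, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.438), with TM7SF2 at 1.17 and SREBF2 at 0.40, and 5 rises without either scrambled replicate or without replicate 1 of both pools. Chaperones of the endoplasmic reticulum showed 4 rises and 6 falls among 16, the same adjusted over the list alone (camera adjusted p = 0.438), with HSPA5 at -0.56, and 2 rises without either scrambled replicate and 0 without replicate 2 of both pools.

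Genes of the actin cytoskeleton and SRF targets showed 12 falls and 3 rises among 19 with both pools, the same adjusted over the list alone, with TAGLN (-1.67), TPM1 (-1.51) and CNN2 (-1.06) lower and CALD1 (1.56) higher. Camera on the actin and SRF genes gave a Benjamini-Hochberg adjusted p = 0.00769, and adjusted p = 0.314 with an estimated correlation. Matrix, protease and integrin genes showed 15 rises and 8 falls among 30, or 16 and 9 adjusted over the list alone (camera adjusted p = 0.163), with LAMA3 (1.68) and TNC (1.39) higher and COL12A1 (-1.97) and THBS1 (-1.80) lower. TGF-beta and BMP targets showed 8 rises and 1 fall among 13, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.506), where ID3 rose (0.50) and the ligand TGFB2 fell (-2.75). WNT targets showed 5 rises and 0 falls among 8, the same adjusted over the list alone (camera adjusted p = 0.148), including RNF43 (1.20) and, uncertain for overlapping exons, AXIN2 (1.76), and 3 rises without scrambled replicate 1. Notch genes showed 3 rises and 4 falls among 10, the same adjusted over the list alone (camera adjusted p = 0.163), with NOTCH3 (2.71), HES1 (2.36) and the ligand JAG1 (1.74) higher and NOTCH1 (-1.12) lower. Epithelial junction genes showed 8 rises and 4 falls among 18, the same adjusted over the list alone (camera adjusted p = 0.438), with TJP3 (2.69) and JUP (1.58, uncertain for exons shared with KRT17) higher and CLDN1 (-1.86) and the splicing regulator ESRP2 (-1.66) lower. Mesenchymal genes showed 3 rises and 2 falls among 7, the same adjusted over the list alone (camera adjusted p = 0.487), with SNAI1 higher (1.06) and VIM lower (-0.43).

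Basal epithelial genes showed 2 rises and 4 falls among 6 (camera adjusted p = 0.57), with KRT15 higher (1.48) and KRT7 lower (-1.17), and luminal and androgen receptor genes 4 rises and 2 falls among 8 (camera adjusted p = 0.816), with STEAP2 (0.97) and FKBP5 (0.64) higher and KRT8 (-1.49) and KRT18 (-1.35) lower, the same counts adjusted over each list alone. Markers of other cell types were mostly near the floor of detection. Of 5 measured leukocyte markers 4 rose with both pools, the same adjusted over the list alone (camera adjusted p = 0.295), including HLA-DRA (3.19) and CD14 (1.66), with 2 rises without replicate 2 of both pools. Of 3 fibroblast markers 1, COL1A1, rose (2.04) and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.181), and the fall was not called without either scrambled replicate or without replicate 1 of both pools, where 0 were. Of 2 neuroendocrine markers and 1 endothelial marker measured, 0 changed, and these lists were too small for camera. Histone genes showed 10 rises and 0 falls among 14, or 11 and 0 adjusted over the list alone, including H2BC4 (1.84), H2AC6 (1.72), H4C8 (1.49) and H1-2 (1.24). Camera on the histone genes gave a Benjamini-Hochberg adjusted p = 4.9e-05, and adjusted p = 0.255 with an estimated correlation. The share of counts from the mitochondrial genome was 3.17% and 3.67% in the scrambled libraries and 4.52% and 4.06% with both pools, and of 13 mitochondrial genes 5 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.368), such as MT-ND5 (0.43). The mitochondrial counts moved to 2 and 0 without scrambled replicate 1, 7 and 0 without scrambled replicate 2, 3 and 1 without replicate 1 of both pools, and 4 and 0 without its replicate 2. Medians, means and camera directions differed in sign, with no list passing, for apoptosis and luminal genes with both pools, for NF-kB, actin, WNT, basal and luminal genes with the TAZ pool, and for DNA replication, matrix, WNT and junction genes with the YAP pool.

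The single knockdowns were set against each other to test the difference directly. CEMIP was lower with the YAP pool than with the TAZ pool (-2.68 ± 0.12), as was TNFRSF21, a death receptor (-1.79 ± 0.07), while ANKRD1 (3.33 ± 0.12) and NTN4 (1.92 ± 0.08) were higher. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2187 genes were higher and 2196 lower with the YAP pool. Without YAP pool replicate 1 the total of 4383 went to 2675 and without its replicate 2 to 2607. Scaled by library totals alone the calls were 1743 higher and 2677 lower, 39.4% against 49.9% higher. Of 21 YAP/TAZ signature genes 13 were higher and 3 lower with the YAP pool, the same adjusted over the list alone (camera adjusted p = 5.79e-10, and adjusted p = 0.299 with an estimated correlation). NF-kB targets were also higher with the YAP pool, 9 against 0 of 16 and 10 against 1 adjusted over the list alone (camera adjusted p = 8.4e-06, and adjusted p = 0.368 with an estimated correlation). Actin and SRF genes were lower, 9 against 2 higher of 19, the same adjusted over the list alone (camera adjusted p = 1.9e-05, and adjusted p = 0.302 with an estimated correlation).

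Across 17192 genes the fold changes with the YAP pool and with the TAZ pool correlated at r = 0.331, against 0.503 in 20 simulations of unchanged groups sharing the same controls, and genes are not independent replicates. The covariance was 0.0646 against 0.0327 in the simulations, a difference of 0.0319. Of the called genes 332 rose and 222 fell with each pool, where independent lists would share 94.1 and 96.1, and 218 changed in opposite directions. The simulations shared a mean of 0.2 in the same direction. They held no changed genes, so that value does not show how many calls the shared controls alone would align. For the TAZ pool and both pools the covariance was 0.262, or 0.229 above the simulated value, with 1303 shared rises, 1281 shared falls and 40 opposite changes, where independent lists would share 376 and 375. For the YAP pool and both pools it was 0.114, or 0.0814 above the simulated value, with 599 shared rises, 555 shared falls and 395 opposite changes, where independent lists would share 277 and 285. Splitting the 2 scrambled libraries would leave 1 for each pool and was not done, so part of each excess may come from the shared controls.

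Combining the pools was compared with each pool alone and with the sum of their log2 effects. CCN1 was lower with both pools than with the YAP pool (-4.69 ± 0.09) or the TAZ pool (-3.38 ± 0.08), and lay 3.55 below the sum of the single effects (-3.55 ± 0.11 on the log2 scale). CLDN11 (-3.64 ± 0.12), MARCHF4, a ubiquitin ligase (-2.89 ± 0.11), and AJUBA, a LIM protein that binds LATS kinases (-2.41 ± 0.10), also lay below the sum, and CEMIP lay above it (4.17 ± 0.15). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1599 genes lay above and 1754 below the sum, 19.5% of those tested. Of these 3353 genes, 2563 had a larger absolute effect with both pools than the absolute sum, in the direction of the sum or against it. The other 790 did not. Against the YAP pool alone 4323 genes were higher and 4255 lower with both pools, including ANKRD1 (-6.46), MARCHF4 (-3.61) and CEMIP (4.45), and against the TAZ pool alone 2984 were higher and 3029 lower, including AMOTL2 (-2.91) and CLDN11 (-2.91). Of the 4365 genes that rose with both pools, 2643 (60.5%) were called in neither single comparison and 2234 (51.2%) were higher than with each pool alone by the tests of those differences. Of the 4372 that fell, the numbers were 2603 (59.5%) and 2266 (51.8%).

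**Figure D3:**
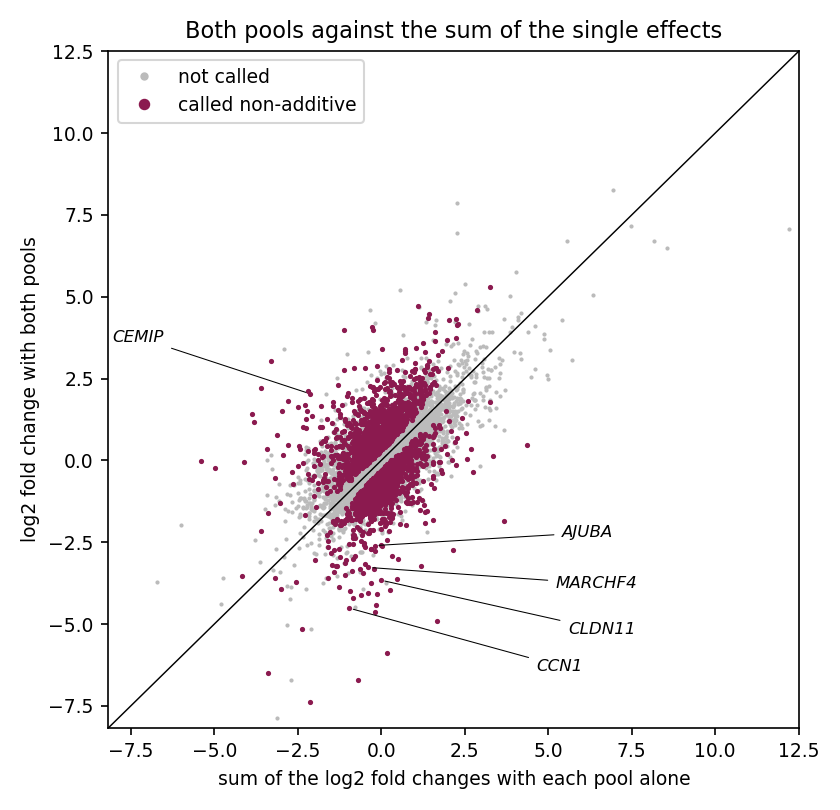
Log2 fold change with both pools (y axis) against the sum of the log2 fold changes with each pool alone (x axis) for 17192 genes, with the line of equality in black and genes called non-additive coloured. CCN1, CLDN11, MARCHF4 and AJUBA lie below the line by 3.55, 3.64, 2.89 and 2.41, and CEMIP lies 4.17 above it.

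Below the sum of the single effects lay 14 of 21 YAP/TAZ signature genes, with 2 above it (15 and 3 adjusted over the list alone), among them CCN2 (-3.37), ANKRD1 (-3.10), AMOTL2 (-2.67) and AXL (-1.21). The 2 above the sum were CCDC80 (0.92) and IGFBP3 (1.78). Camera with Benjamini-Hochberg adjustment gave adjusted p = 5.08e-25, and adjusted p = 0.0459 with an estimated correlation. All 32 mitotic genes of the list lay below the sum, such as BUB1 (-1.22), KIF23 (-1.15), CDK1 (-1.13) and FOXM1 (-1.09). Their camera test gave a Benjamini-Hochberg adjusted p = 6.3e-38, and adjusted p = 0.257 with an estimated correlation. DNA replication genes showed 31 of 40 below the sum and 1 above it, and 34 below adjusted over the list alone (camera adjusted p = 3.4e-19, and adjusted p = 0.302 with an estimated correlation). NF-kB targets showed 11 of 16 below the sum and 0 above, or 14 and 0 adjusted over the list alone (camera adjusted p = 1.14e-08, and adjusted p = 0.257 with an estimated correlation), including CSF2 (-2.35), CXCL2 (-1.71) and NFKB2 (-0.89). Interferon-stimulated genes did not pass (camera adjusted p = 0.488), with a median of -0.07 against the sum. BMF (1.72) and AKR1C3 (2.10) lay above the sum, whereas KRT15 (-0.01) and LIPH (0.08) did not pass the test.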

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

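The test of non-additive genes without the leading words was added after seeing the data, with its bounds written before its own result was seen, and the tests of knockdown depth, of scaling by library totals, of 3′ untranslated region length, of chance among words and of words in the target mRNAs were chosen after the result was seen.

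Results here are singled out because the effect of both pools differed from the sum of the single effects, or because a gene moved in opposite directions under different pools, each by edgeR's test of the difference itself. Among the 3353 non-additive genes, the smallest adjusted p-values were those of CCN1 (-3.55), CLDN11 (-3.64), MARCHF4 (-2.89) and AJUBA (-2.41) below it and CEMIP (4.17) above it. More complete loss of the target mRNAs with both pools is argued against, since YAP1 and WWTR1 were 0.33 and 0.57 higher on the log2 scale with both pools than with their own pool alone, although the WWTR1 value was 0.18 ± 0.13 and did not pass without replicate 2 of both pools, and protein was not measured. With libraries scaled by their totals alone, 3170 of the 3353 genes (94.5%) kept their call and direction. The choice between TMM and totals is therefore argued against as the whole cause. The scaling factors ran only from 0.971 to 1.046, and neither scaling measures total RNA per cell, so other effects of scaling were not tested. Genes without any of the leading words were non-additive at 0.986 of the share among all genes with a 3′ untranslated region, which include them. The leading words are thus argued against as the whole cause. These genes may hold other matches to the siRNAs, whose sequences were not given, so short siRNA matches at large were not excluded. A hypothesis that stays open is that YAP and TAZ may replace each other at shared targets, so that losing both has more effect than the sum. It would need protein levels and rescue with YAP or TAZ alone. Libraries with both pools also received a further siRNA pool, in amounts not given, which cannot be told apart from losing both genes.

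Genes with particular 7-base words in their 3′ untranslated regions were lower after 1 pool, with log2 effects of -0.13 ± 0.01 for CATGAAC after the TAZ pool (1269 genes) and -0.18 ± 0.03 for ACGACCA after the YAP pool (181 genes), and with both pools -0.11 ± 0.02 for CATGAAC and -0.17 ± 0.05 for ACGACCA, but -0.022 ± 0.016 for TTCTTAA and 0.032 ± 0.018 for CTTCTTA, which were lower after the YAP pool. Length and base composition are argued against, since both were in the model that gave t = -10.5 for CATGAAC, below the lowest permuted value of -5.21, and chance among the words is argued against, since 0 of 100 permutations reached such a value. Seed pairing by the siRNA strand complementary to the target would place a match in the target mRNA itself, where only whole 7-base words were searched. The other strand would place the reverse complement of the word there. It occurred 1 time in YAP1 for TTCTTAA and 0 times in their own targets for ACGACCA, TTGACCA and CATGAAC. TTGACCA occurred 0 times in YAP1, ACGACCA and TTCTTAA 1 time each in YAP1, and CATGAAC 1 time in WWTR1 and 2 times in YAP1. YAP1, which was slightly lower with the TAZ pool, was left out of the test of words, so its CATGAAC matches were not weighed. A seed match may cover fewer bases than the word, so the absence of TTGACCA does not exclude a match. By chance at least 3 of 4 words would be present with a probability of 0.0619. Since the siRNA sequences were also not given in the sources used here, seed pairing cannot be told apart from other causes for these 4 words. Of the named genes, SMIM14, TAGLN, MRPS6, KIF3B and MEGF9 (YAP pool) and NTN4 and FKBP4 (TAZ pool) hold a leading word, as do 53.8% of genes lower with the YAP pool against 33.9% of genes not called, and 28.5% against 17.8% for the TAZ pool, an excess expected in part because the words were picked for low values, so a word alone does not tell which falls come from the pools' sequences.

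CEMIP fell with the YAP pool (-2.41) and rose with both pools (2.04), a difference of 4.45. MEGF9 fell with the YAP pool (-1.41) and rose with the TAZ pool (0.73) and both pools (1.65), with differences of 3.06 between both pools and the YAP pool and -2.14 between the YAP and TAZ pools. SMIM14 fell with the YAP pool (-2.15) and rose with the TAZ pool (0.72), a difference of -2.87. TNFRSF21 fell with the YAP pool (-1.26) and rose with the TAZ pool (0.53) and both pools (0.93), with differences of 2.19 and -1.79 in the same order as for MEGF9. S100A9 fell with the YAP pool (-0.71) and rose with both pools (4.08), a difference of 4.79. NTN4 rose with the YAP pool (0.27) and fell with the TAZ pool (-1.65) and both pools (-1.49), with -1.76 between both pools and the YAP pool and 1.92 between the YAP and TAZ pools. For APLN, higher with the YAP pool (0.94) and lower with the TAZ pool (-0.69) and both (-3.96), these differences were -4.89 and 1.63. For PEAR1, at 0.85, -1.15 and -3.75, they were -4.60 and 1.998. For CLDN11, at 0.73, -0.75 and -3.66, they were -4.39 and 1.48. For MARCHF4, at 0.34, -0.72 and -3.27, they were -3.61 and 1.07.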

How the results depend on the processing

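Scaling by library totals and the count without genes that hold a leading word were chosen after seeing the data, and the other alternatives beforehand. DESeq2, its size factors, no low-count filter and the compared libraries alone kept every count within 1.5 times. Over counts and target knockdowns 177 alternative values stayed on the same side or within 1.5 times and 31 moved. Named genes gave 5036 unchanged calls, 226 lost, 13 gained and 6 reversed, and lists 1522, 44 and 58 lost and gained. Requiring a log2 change above 1 left 134 rises and 100 falls with the YAP pool, 144 and 132 with the TAZ pool, 1459 and 980 with both, 2337 between both and YAP, 1161 between both and TAZ, 545 between YAP and TAZ, and 922 non-additive genes, since fewer genes qualify. Leaving out each library in turn gave 442 to 1082 rises and 495 to 1160 falls with the YAP pool, 700 to 1470 and 682 to 1401 with the TAZ pool, 3436 to 4423 and 3485 to 4380 with both, 6699 to 8616, 4368 to 6046 and 2607 to 4402 changed genes for both against YAP, both against TAZ and YAP against TAZ, and 2265 to 3260 non-additive genes. YAP1 ranged from -3.91 to -3.84 with its pool and -3.57 to -3.51 with both, and WWTR1 from -2.61 to -2.23 and -2.23 to -1.53. Non-additive genes numbered 1729 of 7509 without genes that hold a leading word or lack a searched 3′ untranslated region (23.0%, against 23.4% of all 13233 with that region), since fewer were tested. Deviations of the replicate 1 libraries from their group means correlated at 0.0759 (scrambled and TAZ) to 0.214 (TAZ and both). With 2 replicate numbers and no batch in the labels this does not establish pairing, so the number was not used in the tests. With that number as a block the calls were 1802 and 1846 for YAP, 2283 and 2385 for TAZ and 5079 for non-additivity. Directions reversed for values that were not called: WWTR1 non-additivity (-0.21 without replicate 2 of both pools, up to 0.49 without replicate 1), CCN2 with the YAP pool (0.053 without scrambled replicate 1, -0.12 without replicate 2), ANKRD1 with the YAP pool (0.13 without scrambled replicate 1, -0.16 without replicate 2, 0.022 without YAP pool replicate 1) and AXL with the TAZ pool (0.023 by library totals, 0.030 without scrambled replicate 2, -0.080 without replicate 1). The cause was not tested. Genes shared by the YAP and TAZ pools in direction numbered 554, or 518 at 2 log2 CPM and above and 541 with DESeq2 size factors. Of 371 named gene calls, 80 were lost without 1 library. Depth limits the rare markers, such as PTPRC with 1 read over all libraries.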

Other observations

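The gene families and the tests of scaling, leukocyte RNA and siRNA sensing in this part were chosen after the result was seen, while the interferon list, its camera tests and leaving out single libraries were chosen beforehand.

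Beyond the fixed lists, families of genes sharing a symbol stem were counted with both pools, where 50.8% of all genes were called. Over 35 such families and 3 comparisons with scrambled, 105 tests in all, camera with Benjamini-Hochberg adjustment gave 34 below the threshold and 0 with an estimated correlation, where the lowest adjusted p was 0.191. Detoxifying and steroid-metabolising cytochrome P450 and UGT genes showed 20 rises and 2 falls among 30 measured, with a median log2 fold change of 1.04, including CYP4F3 (2.81), CYP4F11 (2.07) and CYP1B1 (1.65). Aldo-keto reductases showed 6 rises and 0 falls among 11. HLA genes, which present peptides to T cells, showed 11 rises and 0 falls among 15, with HLA-DQB1 at 1.90 and HLA-F at 0.77, values that are uncertain because these genes are near-copies of each other. S100 proteins showed 9 rises and 1 fall among 14, such as S100A6 (1.15), and protease inhibitors of the serpin family 10 and 2 among 17, led by SERPING1 (2.15).

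Other families had more falls than rises with both pools, and they too did not pass with an estimated correlation. Subunits of the CCT chaperonin, which folds actin and tubulin, showed 7 falls and 1 rise among 10, including CCT5 (-0.82) and CCT2 (-0.77). Translation initiation factors showed 45 falls and 5 rises among 72, such as EIF3J (-1.05). Mitochondrial ribosomal proteins showed 48 falls and 0 rises among 78, with MRPL3 at -0.77, proteasome genes 31 and 2 among 57, and nucleoporins 19 and 3 among 26, such as NUP107 (-0.96). Hosts of small nucleolar RNAs showed 16 falls and 1 rise among 24, led by SNHG1 (-1.39). Heat shock proteins and DNAJ co-chaperones showed 29 falls and 11 rises among 76, with HSP90AA1 (-1.17) and HSPD1 (-1.08) among the falls.

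Of 26 interferon-stimulated genes 16 rose with the YAP pool, 12 with the TAZ pool (fewer without scrambled replicate 1) and 24 with both pools. With libraries scaled by their totals alone 24 also rose with both pools, which argues against the choice between TMM and totals as the cause. The scaling factors ran only from 0.971 to 1.046, so other effects of scaling were not tested. With an estimated correlation the list did not pass with the TAZ pool (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0547). RNA from leukocytes is argued against as the whole source, since the 10 leukocyte markers together gained at most 0.0171 of the CPM that the interferon list gained in any knockdown library (4.04 against 237 CPM in replicate 2 of both pools), although leukocytes carry these markers at levels not measured here, and this test replaced an earlier one on PTPRC alone (1 read over the 6 knockdown libraries). Reads of single markers were higher, with HLA-DRA at 25 and 18 with both pools against 2 and 2 in the scrambled libraries. It had 6 and 12 with the TAZ pool, where 0 leukocyte markers were called. LAPTM5 had 17 and 21 with the YAP pool and 18 and 19 with both against 9 and 4, but 2 and 4 with the TAZ pool. Its rises leaned on single libraries, with log2 fold changes of 1.16 (YAP pool) and 0.86 (both) without scrambled replicate 2. With both pools CSF1R had 17 and 30 against 5 and 5, and CD14 50 and 79 against 11 and 25. CD79A had 8 and 27 against 0 and 0 but did not pass the filter on low counts, so its difference was not tested. Sensing of the transfected siRNA itself cannot be told apart from an effect of lowering YAP or TAZ, because IFNB1, IFNL1, IFNL2 and IFNL3 reached at most 3 reads in any knockdown library and the siRNA amounts were not given in the sources used here. The scrambled libraries, which also received siRNA, had 2 and 2 reads of IFNB1, 4 and 1 of IFNL1 and 0 of IFNL2 and IFNL3. These transcripts were thus no higher in the knockdown libraries, but reads this few cannot decide the question. Lower YAP or TAZ may itself raise these genes, a hypothesis that would need a control pool with another sequence or rescue of the lowered protein.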
